A study of Cucumis melo with 4 samples.

How the data were processed

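The 4 libraries were made by DAP-seq from melon genomic DNA, 2 with MBP-His-CmNOR and 2 with the MBP-His tag as negative control. Per the labels' protocols, the proteins were purified from E. coli by their His tag, libraries were made with a NEXTflex Rapid DNA-Seq kit, and a PCR-amplified version of the genomic library (ampDAP-seq) is also described. Amplification removes native cytosine methylation, and the labels do not say which libraries used it. Per the submitters' processing notes, MACS2, a peak caller, and deepTools were used. Versions, thresholds, the aligner, the genome build and the gene annotation are not given in the sources used here. How the 2 CmNOR libraries and the 2 controls were combined into 1 list is likewise not given. How strict the calling was decides how many weak sites are listed, and an unstated rule for combining libraries leaves open whether each peak was seen in both.

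The authors deposited 1 table of 5493 peaks with start, end, width in bp, an assigned gene with its coordinates, the signed distance from the nearest peak edge to the gene start, a location class and GO terms, per the file headers. It holds no count, score, fold or p-value. On checking, width equalled end minus start plus 1 and the distance was recomputed exactly from the coordinates in all 5493 rows. The promoter class equalled a distance of at most 3 kb on either side of the gene start in all 5493 rows. The table pairs its gene identifiers with GO terms but not with names, and 0 of the 4510 identifiers matched the RefSeq gene table (assembly USDA_Cmelo_AY_1.0), so genes are given by identifier and GO function. The gene of CmNOR itself was therefore not looked up. No value belongs to 1 library, so the groups enter no test.

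Before the data were examined, a promoter was defined as a peak centre within 2 kb upstream of the assigned gene start, and 23 keyword lists and the tests were fixed. The keyword patterns were written for gene descriptions and were applied to GO term names. As these are worded differently, 12 lists matched no gene, which says nothing of whether such genes have peaks: AP2/ERF, NAC, MADS-box, WRKY, MYB, bHLH, bZIP, homeobox, zinc finger and GATA, cytochrome P450, ribosomal proteins and pentatricopeptide repeat proteins. The other 11 were tested with Fisher's exact test (two-sided) against all 3406 genes with a GO term, with Benjamini-Hochberg adjustment over the 11. The plan had named all annotated genes with a name as the background, so this background departs from it. A further 13 lists written on GO terms and a test of all terms with at least 10 genes were added after the table was opened. The rule for named genes asked for the highest fold enrichment. As no fold is listed, peak width took its place: the 10 widest peaks, the 10 widest within 2 kb upstream, and up to 3 genes with the widest upstream peak for each ripening, hormone and NAC list. The ACC oxidase gene, the pectinesterase inhibitor and beta-galactosidase genes and the other beta-amylase and carotenoid peaks of named genes were added after their values were seen.

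Shares carry 95% exact Clopper-Pearson intervals, and densities exact Poisson intervals. Upstream and downstream counts were compared with an exact binomial test. Chromosome lengths of the build were not used here, so densities rest on the span to the last listed peak, 390 Mb in all. The plan had allowed the chromosome test only with known lengths, so its use here departs from the plan. Chromosome counts were tested with a chi-square statistic and 100000 multinomial draws, and chromosome ends with an exact sign-flip permutation over 12 chromosomes. Peak widths were tested with 100000 permutations. Distances between neighbouring peaks were compared with 1000 random placements of the same widths, uniform on each sequence or within each peak's own 500 kb window. The list test and the placement test were tested on simulated data first. With 150 of the peaks moved beside another, the placement test found the excess in 100% of 100 simulations, and in 98% of uniform ones it made no call. The comparison of both sides of gene starts, the chromosome ends, the neighbour distances, the widths by exon, distal and promoter class, and peak width itself as a measure were chosen after the data were seen. The neighbour limit of 5 kb was set after counts at several limits had been looked at. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

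The planned motif tests, the random placement against gene annotation, the checks on promoter GC content and intergenic length, the replicate overlap and the CmNOR-against-control model were not run, because they need genome sequence, a full annotation or values per library. Alternatives tried were promoters of 1 and 3 kb, any overlap of at least 1 bp in place of the peak centre, peaks of at least the median width, leaving out chr0, other end sizes and other placements.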

Results

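CmNOR is a NAC-family transcription factor of melon (Cucumis melo), named after the NON-RIPENING gene, which acts in fruit ripening in tomato. Its binding sites were mapped by DNA affinity purification sequencing (DAP-seq), in which a tagged protein made in bacteria is mixed with purified genomic DNA fragments and the fragments it retains are sequenced. The 4 libraries fall into 2 groups. In 2 libraries the bait was CmNOR fused to maltose-binding protein and a His tag (MBP-His-CmNOR), and in the other 2 it was the MBP-His tag alone. Per its title, the series asks where CmNOR binds and which core motif it prefers. The values analysed are 1 combined list of 5493 peaks, each with its position, its width, an assigned gene, a location class and the Gene Ontology (GO) terms of that gene. The list has no column per library, so library depth is unknown. It also gives no enrichment or p-value per peak, so CmNOR was not compared with the tag control here, and agreement between the repeats was not measured. No genome sequence was used, so the core motif was not analysed here. Positions are those of the authors' list, whose genome build is not given in the sources used here.

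Most CmNOR peaks were classed as distal intergenic or promoter, and few as exon or intron. The share of the genome in each class was not measured, so these shares are not set against an expectation. Of the 5493 peaks, 2563 were classed as distal intergenic, or 46.7% (95% exact interval 45.3 to 48.0). A further 2210 peaks, 40.2% (38.9 to 41.5), fell in the authors' promoter class, which holds every peak within 3 kb of the assigned gene start on either side. Of these, 967 lay within 1 kb, 673 between 1 and 2 kb and 570 between 2 and 3 kb. Exons held 238 peaks (4.33%) and introns 268 (4.88%) outside that zone, which itself takes in the first 3 kb of each gene. The remaining classes were small, with 169 peaks within 3 kb downstream of a gene, 41 in 3' UTRs and 4 in 5' UTRs. These intervals and all others given for shares of peaks or genes cover counting error only, since the list has no replicate values.

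**Figure D1:**
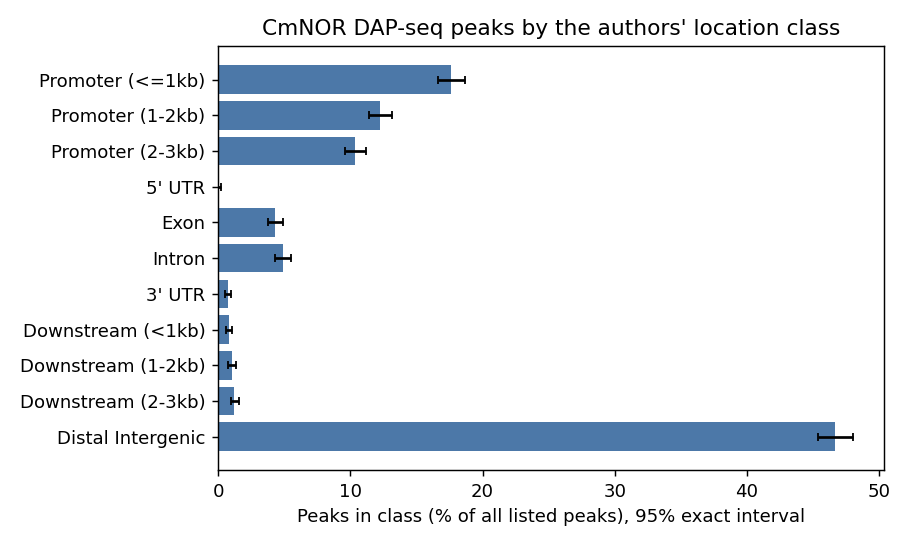
Share of the 5493 CmNOR peaks in each of the authors' location classes (horizontal axis, percent of peaks). Bars show the share and whiskers the 95% exact binomial interval, and distal intergenic sequence is the largest class at 46.7%.

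About as many promoter-class peaks lay inside or past the assigned gene as upstream of it. By peak centre, 1119 of the 2210 were upstream of the gene start, or 50.6% (95% exact interval 48.5 to 52.7), 798 were inside the gene (36.1%) and 293 lay beyond its end (13.3%). The class named 2105 genes, 46.7% of the 4510 genes assigned to any peak, and 1048 of those 2105 had no peak centre in the 3 kb upstream. A narrower definition, a peak centre within 2 kb upstream of the gene start, held 775 peaks (14.1% of all, 13.2 to 15.1) and 771 genes. That definition was fixed before the data were examined and is the one used for the gene lists.

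Peaks were spread over several kb on both sides of gene starts, with the fullest 250 bp bin, 125 peaks, at 750 to 1000 bp upstream. Within 1 kb, 436 peak centres lay upstream and 368 downstream, a ratio of 1.18 (exact binomial test, two-sided, p = 0.018, adjusted p = 0.054 over the 3 distance ranges). By the same exact test the counts were 339 and 337 between 1 and 2 kb (p = 0.97) and 298 and 329 between 2 and 3 kb (p = 0.23). In genes of at least 3 kb, where the whole downstream range lies in the gene, the ratio within 1 kb was 1.02 (180 against 176, exact binomial p = 0.87). In those genes it was 1.10 between 1 and 2 kb (179 against 163, exact binomial p = 0.42) and 0.763 between 2 and 3 kb (132 against 173, exact binomial p = 0.022, adjusted p = 0.066). Peaks covered the gene start itself in 204 cases, 3.71% of all peaks (3.23 to 4.25). This comparison was chosen after the data were seen.

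**Figure D2:**
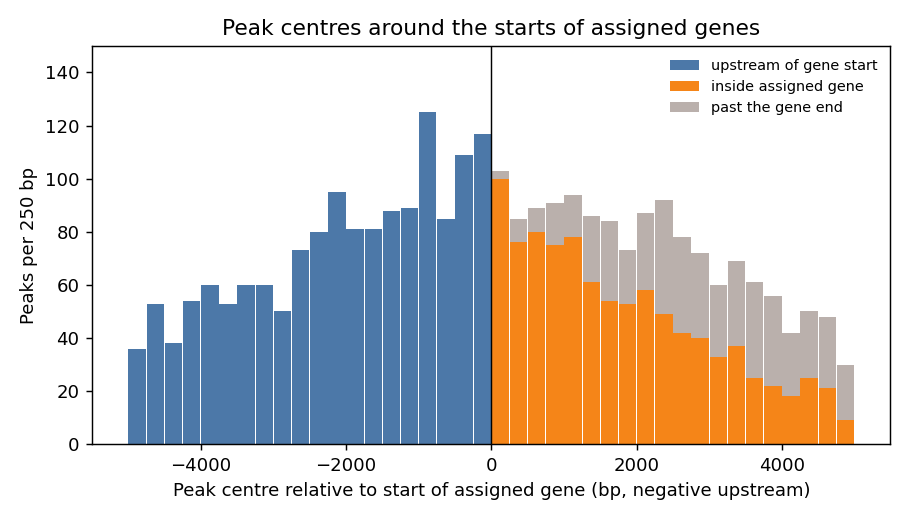
Number of peak centres per 250 bp (vertical axis) by distance to the start of the assigned gene in bp (horizontal axis, negative upstream), coloured by whether the centre is upstream, inside the gene or past its end. Counts are 117 in the 250 bp before the start and 103 in the 250 bp after it, the highest bin holds 125 at 750 to 1000 bp upstream, and the outermost bins hold 36 and 30.

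All 12 numbered chromosomes carried CmNOR peaks, and each had more per Mb at its ends than in its interior. Densities ran from 13.7 peaks per Mb on chromosome 9 to 16.3 on chromosome 2, taking the span up to the last listed peak as the length. A difference among the 12 numbered chromosomes did not pass the test (chi-square 18.1, p = 0.081 from random multinomial draws). With the sequence named chr0 included the test passed (chi-square 280, p = 1e-05, the smallest 100000 draws can give), because chr0 held 154 peaks, or 4.36 per Mb (3.70 to 5.11). In melon assemblies chr0 conventionally collects unplaced sequence. In the outer 20% of the 12 chromosomes the density was 18.8 ± 1.88 peaks per Mb (SD, n = 12 chromosomes) against 14.2 ± 1.08 in the inner part. The outer value was higher in 12 of 12 chromosomes (exact sign-flip permutation test, two-sided, p = 0.000488, the smallest 12 pairs can give). Both tests of chromosome ends were chosen after the data were seen. Gene density along the chromosomes was not measured, so a preference of CmNOR for the ends cannot be told from the layout of genes.

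Peaks at chromosome ends lay closer to gene starts than peaks in the interior. In the outer 20%, 61.8% ± 6.58 of peaks (SD, n = 12 chromosomes) belonged to the authors' promoter class, against 33.8% ± 3.79 in the inner part. This difference of 28.0 percentage points was seen in 12 of 12 chromosomes (exact sign-flip permutation test, two-sided, p = 0.000488). The share fell from 64.4% in the first 10% of the span to 23.5% at 50 to 60% and returned to 59.9% in the last 10%, while density went from 18.7 to 12.5 and back to 18.9 peaks per Mb. The median distance from peak to assigned gene start was 2001 bp in the first 10% and 7566 bp at 50 to 60%. Without a measure of gene density, these differences cannot be assigned to CmNOR rather than to the layout of genes.

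**Figure D3:**
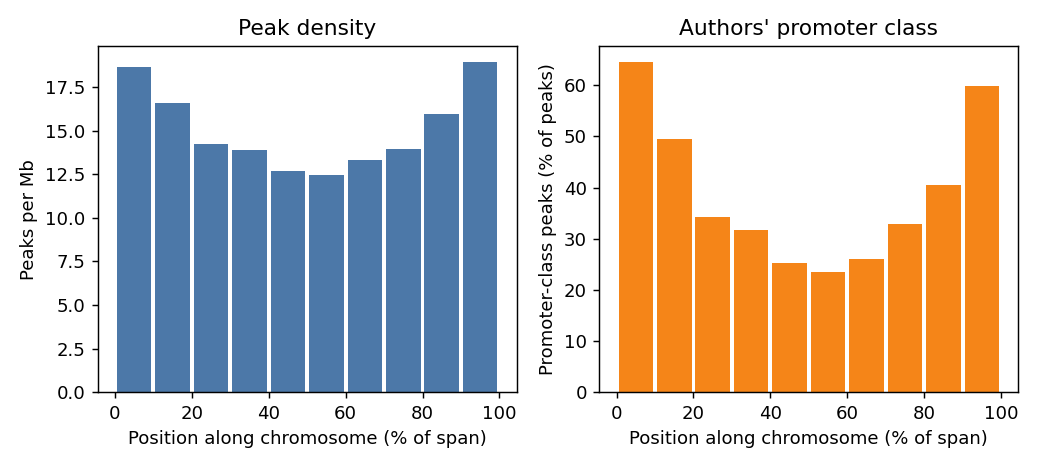
Peaks per Mb (left, vertical axis) and the percentage of peaks in the authors' promoter class (right, vertical axis) in steps of 10% along the 12 numbered chromosomes, pooled, by position in percent of the span up to the last listed peak (horizontal axes). Density dips from 18.7 to 12.5 peaks per Mb at 50 to 60% of the span while the promoter-class share dips from 64.4% to 23.5%.

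Genes of carotenoid and sugar metabolism were among those with a CmNOR peak close upstream. MELO3C002692.2, annotated with the desaturation of zeta-carotene to a cis form of the carotenoid lycopene, had a peak on chromosome 12 at 21986935 to 21987543, 475 bp upstream of the gene at 21988018 to 21990993. MELO3C020744.2 on chromosome 8, annotated to carotenoid biosynthesis, had 2 upstream peaks, 693 and 1435 bp from its start. In sugar metabolism, the beta-fructofuranosidase (invertase, which splits sucrose) gene MELO3C005560.2 had a peak on chromosome 9, 565 bp upstream. The beta-amylase (starch breakdown) gene MELO3C006362.2 on chromosome 6 had 1 peak over its start and 1 lying 617 bp upstream. MELO3C026917.2 on chromosome 11, a kinase gene annotated with the response to sucrose, had a peak 1256 bp upstream. MELO3C015601.2, another kinase gene of the response to sucrose, had one 1356 bp upstream. The carotene desaturase gene MELO3C024674.2 had its peak in an exon, 12129 bp from its start. The sucrose synthase genes MELO3C010300.2, MELO3C015552.2 and MELO3C020357.2 had peaks 2461 and 6901 bp downstream and 5022 bp upstream of their starts. In all, 4 of the 9 sugar and starch genes had a peak centre within 2 kb upstream. So did 2 of the 3 genes in the carotenoid and chlorophyll list, each annotated to carotenoids. Across all 3406 GO-annotated genes in the list the share was 605, or 17.8% (95% exact interval 16.5 to 19.1). Neither list passed Fisher's exact test (two-sided, odds ratio 9.29, p = 0.083 for carotenoids and odds ratio 3.72, p = 0.059 for sugars, adjusted p = 0.458 for both over 11 lists). A list of 3 genes could not pass after adjustment here even with an upstream peak at every gene, so the carotenoid result decides nothing.

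The cell wall genes with an upstream peak were annotated as pectinesterases, a pectate lyase, a pectinesterase inhibitor and a beta-galactosidase. The list holds genes for pectinesterases and their inhibitors, pectate lyases, polygalacturonases, beta-galactosidases and cellulose synthases. Of its 37 genes, 5 had a peak centre within 2 kb upstream, or 13.5% (4.54 to 28.8, odds ratio 0.721, Fisher's exact p = 0.67, and an odds ratio of 1.13 with a promoter of 1 kb). Pectate lyase cuts the pectin backbone, and its gene MELO3C028783.2 on chromosome 1 had a peak 381 bp upstream. The pectinesterase genes, whose products remove methyl groups from pectin, were MELO3C005532.2 on chromosome 9, with a peak 773 bp upstream, and MELO3C006207.2 on chromosome 6, with one 688 bp upstream. The others were the pectinesterase inhibitor gene MELO3C019686.2 on chromosome 11, with a peak 52 bp upstream, and the beta-galactosidase gene MELO3C030444.2 on chromosome 4, with one 736 bp upstream. By the authors' promoter class 12 of the 37 had a peak, 32.4% against 49.0% of all GO-annotated genes (odds ratio 0.496, Fisher's exact p = 0.047, adjusted p = 0.52). In the list for ethylene, the ripening hormone, the single member was an ACC oxidase gene, MELO3C007425.2, whose peak lay past the gene's end, 3669 bp from its start. Of the 7 genes in the aroma list, annotated as terpene synthases or cinnamyl-alcohol dehydrogenase, 0 had a peak centre within 2 kb upstream, which allows a share of up to 41.0%. The terpene synthase gene MELO3C014392.2 had a peak 2024 bp upstream, just past that limit. By the authors' promoter class 3 of the 7 had a peak.

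Hormone genes with upstream peaks numbered 5 for abscisic acid, 5 for auxin and 1 for the other hormones listed. Of 17 abscisic acid genes, 5 had a peak centre within 2 kb upstream, or 29.4% (10.3 to 56.0, odds ratio 1.94, Fisher's exact p = 0.21, and an odds ratio of 0.579 with a promoter of 1 kb). MELO3C034428.2 on chromosome 10 carries terms for the response to abscisic acid and water deprivation, and had a peak 962 bp upstream. MELO3C002215.2 on chromosome 12, a calcium-dependent protein kinase gene of abscisic acid signalling, had one 636 bp upstream. MELO3C032204.2 on chromosome 6, annotated with negative regulation of transcription and the same pathway, had one 1154 bp upstream. Of 33 auxin genes, 5 had an upstream peak, or 15.2% (odds ratio 0.825, Fisher's exact p = 0.82). A peak covered the start of MELO3C002378.2 (response to auxin, chromosome 12). Peaks lay 916 bp upstream of MELO3C027346.2 on chr0, whose product conjugates auxin to amino acids, and 1102 bp upstream of MELO3C025758.2 on chromosome 11, annotated with DNA binding and auxin signalling. Of 19 genes for gibberellin, cytokinin, brassinosteroid or jasmonate, 1 had a peak centre within 2 kb upstream, the cytokinin dehydrogenase gene MELO3C026323.2 on chromosome 8, at 1768 bp. By the authors' promoter class the counts were 11 of 17 for abscisic acid, 14 of 33 for auxin and 9 of 19 for the other hormones, against 49.0% of all GO-annotated genes. The comparison lists gave 32 of 169 for protein kinases (18.9%, odds ratio 1.09), 2 of 11 for photosystem genes and 0 of 2 for the histone list.

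**Figure D4:**
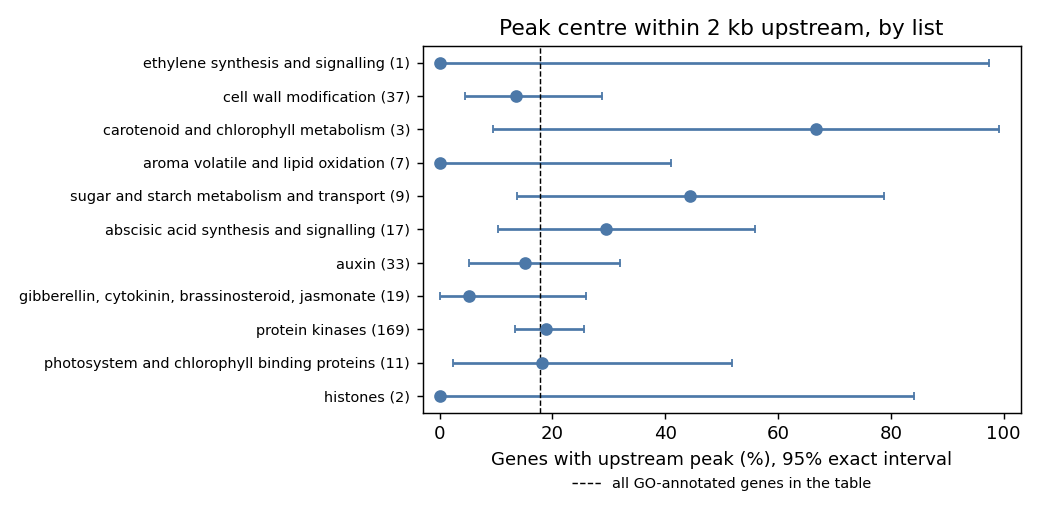
Percentage of each list's genes with a peak centre within 2 kb upstream (horizontal axis), with the number of list genes in brackets. Points show the share, whiskers the 95% exact binomial interval and the dashed line the 17.8% found over all GO-annotated genes, which lies inside every interval.

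Of the 11 lists with members, 0 passed Fisher's exact test after adjustment and 0 had an unadjusted p under 0.05 when genes with an upstream peak were compared with the other GO-annotated genes in the list of peaks. The ethylene, histone and carotenoid lists, with 1, 2 and 3 genes, were too small to pass after adjustment whatever their peaks. For these lists the outcome says nothing. The aroma list could not pass for few upstream peaks either, since 0 of its 7 genes gave a Fisher's exact p of 0.62. Among the 177 GO terms carried by at least 10 genes, 0 passed after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 4 terms. The odds ratio was 0.299 for transaminase activity, 0.387 for protein dimerization activity, 0.428 for pyridoxal phosphate binding and 3.88 for carboxypeptidase activity. The transaminase and pyridoxal phosphate terms are not separate results, since a group of 50 genes carries both. The carboxypeptidase value rests on 5 of 11 genes. The comparison sets genes with an assigned upstream peak against genes whose assigned peaks lie elsewhere, not against melon genes without an assigned peak. In simulated data, members of the 37-gene cell wall list had 3 times the weight of other genes in a draw of targets without replacement. The test found the list in 85% of 100 simulations, and at a weight of 2 in 28%. Such a weight raises the chance of being a target by less than the weight itself. Among the lists, power was simulated only for this one and the protein kinases, so it is not known for the others.

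Exon peaks were wider and distal intergenic peaks narrower than the other peaks. Widths ran from 298 to 1765 bp with a median of 421 bp. The median was 426 bp within 2 kb upstream of a gene start and 421 bp elsewhere (permutation test, two-sided, p = 0.48). In the authors' promoter class it was 428 bp against 418 bp (permutation p = 0.034, adjusted p = 0.057 over 5 comparisons). Exon peaks had a median of 449 bp against 421 bp (permutation p = 0.0029, adjusted p = 0.015 over 5 comparisons), and distal intergenic peaks one of 416 bp against 428 bp (permutation test, adjusted p = 0.021). These last comparisons were chosen after the data were seen. Of the 10 widest peaks, 6 were distal intergenic, against 46.7% of all peaks. The widest, 1765 bp at 3179849 to 3181613 of chr0, was assigned to the transaminase gene MELO3C027610.2. The next, 1711 bp on chromosome 8, began 849 bp inside MELO3C008968.2, annotated with sequence-specific DNA binding, and ran past its end. The other distal ones were assigned to MELO3C028132.2 (ATP binding, 1410 bp), MELO3C018163.2 (chloroplast RNA modification, 1409 bp), MELO3C013782.2 (protein dimerization, 1396 bp), MELO3C033520.2 (ubiquitin-specific protease, 1239 bp) and MELO3C029644.2 (transaminase, 1224 bp). A peak of 1361 bp in the downstream class was assigned to the transporter gene MELO3C034180.2. The 10 widest peaks within 2 kb upstream began with those of MELO3C020902.2, which has no GO term (1434 bp), MELO3C007423.2, a chloroplast protein gene (1416 bp), MELO3C017298.2, a malate transport gene (1107 bp), and MELO3C012281.2, an amino acid transporter gene (1056 bp). The others belonged to the stress-response kinase gene MELO3C014736.2 (1018 bp), the actin-bundling gene MELO3C018887.2 (1010 bp), the metal ion transport gene MELO3C008011.2 (999 bp), MELO3C027643.2 without a GO term (961 bp), the nucleic acid binding gene MELO3C015164.2 (936 bp) and the serine carboxypeptidase gene MELO3C010046.2 (911 bp). Width is not a measure of enrichment, and peaks are not replicate samples, so these tests describe this list only.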

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

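All alternatives below were chosen after seeing the data, except the promoters of 1 kb for location, widths and lists, and the promoter of 3 kb and the overlap rule for location. The share of peaks upstream of a gene, 14.1% at 2 kb, was 7.94% at 1 kb, 19.5% at 3 kb and 17.4% with any overlap of at least 1 bp. The upstream-to-downstream ratio within 1 kb, 1.18 over all genes, was 1.02 in genes of at least 3 kb (exact binomial p = 0.87). The cause was not tested. It stayed between 1.16 and 1.22 by peak edge, without chr0 and in peaks of at least median width. The difference in density between sequences ended without chr0 (chi-square 18.1, p = 0.081), so it rested on chr0. Neighbouring pairs were 1.17 times those of uniform placement within 5 kb but 0.914 times within 1 kb (106 pairs, placements 86 to 151). Placement allows overlaps that a peak caller would join, and only 5 listed pairs overlap. In 24 alternatives the result kept its direction and its side of the threshold, or moved by less than its interval, among them those of both tests of chromosome ends. Lists passing stayed at 0 under each of 5 alternatives (smallest adjusted p from 0.17 to 0.65) and terms passing at 0 under both of theirs. The lowest of these values belongs to the transaminase list, whose genes were singled out for few upstream peaks. With a promoter of 1 kb, the cell wall list went from an odds ratio of 0.721 to 1.13 and the abscisic acid list from 1.94 to 0.579, and the photosystem and protein kinase lists also crossed 1 under an alternative, so no direction can be given for these 4. The carotenoid list had an unadjusted Fisher's exact p of 0.026 with a promoter of 1 kb and 0.024 in peaks of at least median width (adjusted p = 0.29 and 0.27). No paired analysis was possible because the list has no column per library. For the same reason leaving out a replicate, every alternative by fold, score or q, the reciprocal overlap and the edgeR and DESeq2 fits were not run, nor were the motif alternatives. The alternative that counts any assigned peak was not run because it makes every gene a target. Unknown depth limits what can be said of genes without a listed peak.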

Other observations

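The test of the nearest gene start was set down before its result was seen, and the other values and tests in this part were chosen after the data were seen. Some CmNOR peaks lay far from the gene they were assigned to. MELO3C033108.2 on chromosome 8 was the assigned gene of 14 distal peaks, 56.8 to 513 kb away, and MELO3C003905.2 on chromosome 5, annotated as a glycine-tRNA ligase, of 12 peaks 33.3 to 457 kb away. MELO3C005063.2 on chromosome 9, annotated to the RNA polymerase III factor TFIIIB, was the assigned gene of 11. In all, 187 peaks (3.40%) lay over 100 kb from the assigned start, and 28 genes had 5 or more peaks. The densest windows were at 3 to 4 Mb of chromosome 4 with 32 peaks and 2 to 3 Mb of the same chromosome with 30, against a mean of 14.96 per Mb.

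A group of 50 genes carried exactly the same 3 terms, catalytic activity, transaminase activity and pyridoxal phosphate binding. Their peaks were distal intergenic in 40 of 63 cases, 63.5%, against 42.3% for the other GO-annotated genes. A p-value is not given for this, since the genes were singled out for having few upstream peaks and a high distal share is largely the other side of that. Their median length was 1777 bp, against 3379 bp for the other GO-annotated genes. Whether these are ordinary enzyme genes was not examined. The 1104 genes without any GO term were short, with a median of 448 bp against 3336 bp, and 58.7% of their peaks were distal intergenic against 42.6%.

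Among the 13 lists written after the table was opened, 0 passed. Upstream peaks were found in 13 of 102 genes with transcription factor activity, 8 of 58 with cell wall terms, 11 of 44 with defense response, 8 of 27 with oxidative stress or peroxidase terms and 12 of 55 with ubiquitin terms. They were found in 9 of 49 ribosomal genes, 5 of 27 photosynthesis genes, 3 of 16 fatty acid genes, 4 of 26 transposon-derived genes, 1 of 11 chlorophyll and tetrapyrrole genes, 0 of 2 with ethylene terms and 0 of 1 with ripening or senescence terms. The 4 of 65 with transaminase activity gave the only unadjusted p under 0.05 (Fisher's exact test, odds ratio 0.299, p = 0.013, adjusted p = 0.17). This list includes the group of 50 genes singled out above for few upstream peaks, so its p-value is no independent support. As 1 of the 177 GO terms it did not pass.

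Neighbouring peaks 1 to 5 kb apart were more numerous than random placement gives. There were 389 such pairs among 5493 peaks, against a median of 308 in 1000 uniform placements (range 250 to 366). Placement within each peak's own 500 kb window, which keeps the regional density, mostly gave fewer pairs within 5 kb. The observed count was 1.11 times theirs (495 against a median of 445, range 389 to 507, one-sided simulated p = 0.0070, not an exact test). In 100 kb windows it was 495 against 452 (range 393 to 514). Some of these placements reached the observed count within 5 kb, and density on a finer scale than 100 kb was not tested. Density of peaks as the explanation therefore stays open. Pairs 1 to 5 kb apart were 1.20 times the placements in 500 kb windows (389 against 323, range 280 to 387). In 100 kb windows they were 389 against 327 (range 279 to 384), so no placement in either window size reached their count. Pairs under 1 kb were 106 against 122 in 500 kb windows. Both limits were set after pair counts had been seen, and splits over 1 kb apart are not excluded. Wide sites split by the peak caller therefore stay open, as does duplicated sequence that shares reads, because no genome sequence was used, and no biological explanation was tested.

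Whether chr0 is sparse in peaks because it holds few genes stays open, since no gene density was measured. Its promoter-class share was 20.8%, and the 83 windows of 1 Mb on the numbered chromosomes with a share no higher than that held 13.1 peaks per Mb (95% exact interval 12.3 to 13.9) against 4.36 on chr0. That share comes from the peaks themselves and is only a proxy for gene density, and windows chosen by it include some that are low by counting error, so the value does not decide. Unresolved or repeated sequence on chr0 was not examined, and no biological explanation was tested.

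Of 506 peaks classed by an exon or intron, 177 (35.0%, 95% exact interval 30.8 to 39.3) were assigned to a gene other than the one holding them, 84 of 238 in exons and 93 of 268 in introns. Assignment by the nearest gene start is a candidate explanation: among the 37 whose host gene has coordinates in the list, the host start was nearer in 0. A search of the list by assigned gene misses those 177 sites for the genes that hold them.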
